A study of Rattus norvegicus with 10 samples.

How the data were processed

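Left hippocampi of 10 female TgF344-AD rats, 5 treated with ibudilast and 5 untreated, were profiled by RNA sequencing. Per the labels, RNA was isolated with a column kit and made into strand-specific mRNA libraries. Whether the counting used the strand is not given in the sources used here, so overlapping and antisense genes, and close paralogs such as ribosomal protein genes and their copies, carry that uncertainty. Groups were taken from the treatment labels and replicate numbers from the titles.

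The deposited expected counts per gene are estimated counts made by the authors, with bcl2fastq 2.17, Bowtie2 2.1.0, RSEM 1.2.15 and the rn6 genome build named in the submitters' processing notes. The annotation and any filter are not given in the sources used here. The deposited signal table holds TMM-scaled CPM made by the authors, with edgeR named in the submitters' processing notes. TMM-scaled values recomputed from the rounded counts matched 99.9% of that table within 0.1%. The table lists 17168 genes, of which 25 symbols had been turned into dates by a spreadsheet, and all 25 were recovered by matching. Between 10.6% and 11.3% of the expected counts per library were not whole, and all were rounded before testing.

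Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg adjusted p under 0.05), which left 11682 genes. Group means and SDs are in TMM-scaled CPM, and standard errors follow from the quasi-likelihood statistic. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) over 32 lists with at least 5 tested members, and the adjusted p covers these 32. Where no other setting is named, camera has the preset correlation. Each list score, the mean z-score of log2 CPM, was compared by a two-sided exact permutation test, with Benjamini-Hochberg adjustment over lists. That test asks whether a score differs between the groups, not whether the list differs from other genes. The lists, these tests and most alternatives were set before the data were examined. Lists of neocortical, cerebellar, hippocampal principal cell and pituitary markers, and the gene families, were written after.

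Named genes followed a rule set before the data were examined. It took the 12 largest changes in each direction among called genes with a mean of at least 1 CPM, up to 4 called members of each list (or the 2 of smallest p where none passed), and fixed genes that included App, Pde4b, Mif and Tlr4. Some of the genes that the rule takes are not reported here. The markers of the later lists, Ttr, the gene families, Tyro3, and list members outside that rule, such as Igf1, Slc4a4, Tlr2, Tnnt1, Neu4 and Slc32a1, were named after their values were seen.

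Alternatives covered other scaling factors and filters, unrounded counts, DESeq2 1.42.0, limma-voom, robust edgeR, limma-trend on the deposited CPM, 1 surrogate variable from sva 3.50.0, the replicate number as a block, the range of the animal tag, fry, and each library left out. Added after seeing the data were sets of libraries left out, covariates from region markers, thinning to the smallest total, removal of 3 ribosomal RNA entries, and removal of a trend with gene span by a loess offset. Span came from the GRCr8 RefSeq table and was found for 98.4% of tested genes. Since the counts use rn6, span is an approximation, and no coordinates are given.

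On simulated counts for 11564 genes with the depth and spread of this comparison and 200 changed genes, edgeR recovered 18% of those changed 1.5-fold and 68% of those changed 2-fold, with 1 false call among 87. With no changed genes it made 0 calls. Simulated genes varied independently of each other, so false calls from variation that genes share were not assessed. Total counts per library were between 6960066 and 10121571. No male animals were analysed here.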

Results

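RNA from the left hippocampus of 10 female TgF344-AD rats was sequenced, 5 given ibudilast and 5 left untreated. TgF344-AD rats carry human transgenes, among them that for the amyloid precursor protein, and are used as a model of Alzheimer disease. Ibudilast is an oral inhibitor of several cyclic nucleotide phosphodiesterases, and it also acts on the cytokine MIF and the receptor TLR4. Treatment started at 5 months of age and lasted 6 months, and all rats were 11 months old at dissection. The titles give each library its own animal tag. Total estimated counts ran from 6960066 to 8204390 in the untreated group and from 7553804 to 10121571 in the ibudilast group. The difference in totals had an exact two-sided permutation p = 0.0556.

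The comparison asks which hippocampal genes differ in level between treated and untreated transgenic females. Camera called lists of homeostatic microglia markers, ribosomal proteins, chaperones, the proteasome and the respiratory chain lower with ibudilast, and lists of clock genes, of ibudilast targets and phosphodiesterases and of markers of neighbouring brain regions higher. These calls used a preset correlation between genes, and with an estimated correlation each of these lists had an adjusted p = 0.541 and did not pass. Of 11682 genes tested, 4497 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2337 of them higher and 2160 lower. At least a 2-fold change was seen for 730 of the higher and 284 of the lower genes. The groups did not overlap at 24.3% of the tested genes, where chance gives 0.794%. Without ibudilast 3, ibudilast 5 and untreated 1, in which cerebellar, meningeal or choroid plexus markers stood out, 3112 genes changed, 1755 higher and 1357 lower. That fit kept ibudilast 2 and ibudilast 4, which had the highest neocortical scores, and ibudilast 1, which had the most of the pituitary transcript Prl. With a score of neocortical markers as a covariate edgeR called 1740 genes, and with a score of hippocampal neuron markers it called 0, with 1552 at an unadjusted p under 0.05. These fits, and the markers behind both scores, were chosen after the data were seen.

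Markers of neighbouring brain regions differed between the groups. In the list for thalamus, striatum and cortex 9 of 20 members rose, and 1, the troponin gene Tnnt1, fell (10 and 1 adjusted over the list alone). Cux2, a marker of upper cortical layers, went from 26.9 ± 5.98 to 124 ± 31.8 CPM (counts scaled to library size with TMM factors; SD, n = 5 each), and Lamp5, a gene of cortical neurons, from 65.2 ± 18.4 to 165 ± 59.0 CPM. The list had a camera adjusted p = 0.0131, an adjusted p = 0.541 with an estimated correlation, and an exact permutation adjusted p = 0.0282. In the dentate granule and CA field list 5 of 18 fell and 1, Cacng5, rose, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.108, exact permutation adjusted p = 0.0794). In lists written after the values were seen, 15 of 20 hippocampal principal cell markers fell and 8 of 17 neocortical markers rose. Tbr1, a cortical transcription factor gene, stood at 8.61 to 21.2 CPM in untreated and 27.4 to 126 CPM in ibudilast libraries. Cerebellar markers stood out in ibudilast 3, where Fat2 and Gabra6, genes of cerebellar granule cells, reached 1196 and 449 CPM against at most 5.59 and 0.490 CPM in the other 9 libraries. The log2 fold changes of Fat2, Cbln1 and Car8 were 9.0, 4.14 and 4.20 with all libraries and 2.36, 1.59 and 0.15 without ibudilast 3. Car8 did not pass without ibudilast 3 or any 1 untreated library.

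**Figure D1:**
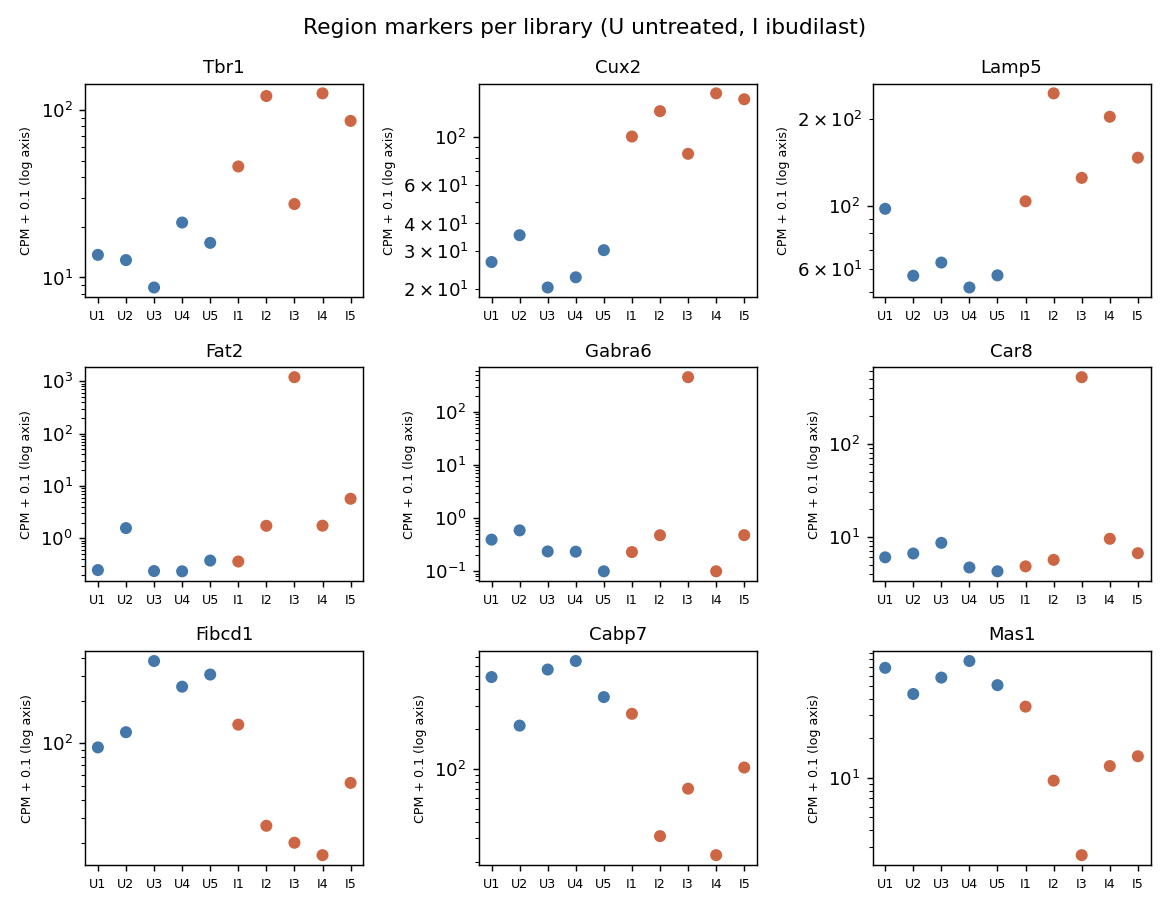
CPM plus 0.1, on a log axis, of 9 region markers in each untreated (U) and ibudilast (I) library. Tbr1, Cux2 and Lamp5 mark neocortex, Fat2, Gabra6 and Car8 cerebellum, and Fibcd1, Cabp7 and Mas1 hippocampal neurons, and Fat2 reached 1196 CPM in ibudilast 3.

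Among the genes with the largest rises, Sema3a, which encodes a secreted axon guidance cue, went from 0.498 ± 0.451 to 13.1 ± 4.98 CPM (SD, n = 5 each), a log2 fold change of 4.65 ± 0.55 (SE; edgeR adjusted p = 0.000688). Dpp4, which encodes a cell-surface peptidase, went from 0.342 ± 0.176 to 4.97 ± 2.31 CPM. The synaptic vesicle calcium sensor gene Syt2 had a log2 fold change of 4.83, or 3.84 without ibudilast 3, where it stood at 287 CPM. Among the largest falls, the interferon-induced GTPase gene Mx1 went from 18.1 ± 11.7 to 2.56 ± 1.67 CPM. The inducible chaperone gene Hspa1a had a log2 fold change of -2.70 ± 0.71 (SE). It was -3.33 without ibudilast 1 and -2.36 without ibudilast 3, where Hspa1a stood at 0 CPM. Trhr, the receptor gene for thyrotropin-releasing hormone, fell by 2.42 on the log2 scale.

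Most homeostatic microglia markers were lower in the ibudilast libraries. Of 16 homeostatic microglia markers 13 fell and 3 did not pass, with a median log2 fold change of -0.89, and 13 fell adjusted over the list alone. Aif1, which encodes the microglial protein IBA1, went from 36.4 ± 11.1 to 13.1 ± 2.63 CPM (SD, n = 5 each), and the complement gene C1qa fell by 1.35 on the log2 scale. Of 16 disease-associated microglia genes 7 fell and 1, the growth factor gene Igf1, rose (8 and 1 adjusted over the list alone). Apoe, which encodes the main lipid carrier of the brain, went from 6432 ± 1245 to 2957 ± 674 CPM, and the microglial receptor gene Trem2 from 21.9 ± 5.19 to 10.2 ± 3.94 CPM. The libraries are of tissue, so the cells that the Apoe transcripts came from were not resolved. The lists had camera adjusted p = 9.23e-06 and 0.00649, exact permutation adjusted p = 0.0282 for each, and adjusted p = 0.541 for each with an estimated correlation. With the hippocampal marker score as a covariate, where edgeR called 0 genes, the homeostatic list still passed camera, with a median of -0.70. The disease-associated list did not (median -0.24, camera adjusted p = 0.115). That score varies with treatment, so a call kept under it excludes nothing. With the neocortical score the homeostatic list passed (median -0.98, camera adjusted p = 7.4e-06), and the disease-associated list did not (median -0.40, camera adjusted p = 0.16).

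Other immune lists had members on the lower side. In the list for MHC antigen presentation 7 of 16 fell and none rose, among them RT1-DMa, which helps to load peptide onto class II molecules, with a log2 fold change of -1.30 ± 0.20 (SE; edgeR adjusted p = 0.00125). In the complement list 8 of 18 fell and none rose, and in the interferon list 9 of 21 fell and 1, Stat2, rose. Adjusted over the list alone, these counts were the same. Camera gave adjusted p = 0.00132 for MHC and for complement and 0.00649 for interferon, and the adjusted p was 0.541 for each with an estimated correlation. Exact permutation of the scores passed for complement (adjusted p = 0.0391) but not for interferon (0.0544) or MHC (0.0677). In the TLR4 and NF-kB list Nfkbia, Tlr2, Vcam1 and Casp1 fell and Traf6 rose of 17, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.192). Casp1 did not pass without untreated 2, ibudilast 2 or ibudilast 4, and its log2 fold change ran from -1.36 to -0.84 with 1 library left out. Tlr4 itself stood at 1.36 ± 0.35 and 1.73 ± 0.89 CPM (SD, n = 5 each; edgeR adjusted p = 0.47). In the list for blood and immune cells Ncf1 fell of 5, with 0 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.25). Ncf1 passed with 1 library left out only when that was untreated 4, untreated 5 or ibudilast 1, with log2 fold changes from -0.67 to -0.38 over the 10 such fits.

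Lists of ribosomal protein, ubiquitin-proteasome, heat shock and respiratory chain genes had members on the lower side. Of 76 cytosolic ribosomal protein genes 75 fell, with a median log2 fold change of -0.66, and adjusted over the list alone 76 did. Rps28 went from 132 ± 28.9 to 64.8 ± 7.63 CPM (SD, n = 5 each). Of 41 ubiquitin-proteasome genes 25 fell (27 adjusted over the list alone), and of 35 heat shock and unfolded protein response genes 17 fell (17 adjusted over the list alone), with none rising in either list. Hspa5, which encodes the main chaperone of the endoplasmic reticulum, went from 505 ± 49.1 to 293 ± 16.8 CPM. In oxidative phosphorylation 31 of 43 genes fell and none rose, or 32 and 1 adjusted over the list alone, and Uqcrq, which encodes a subunit of respiratory complex III, went from 119 ± 17.9 to 67.7 ± 8.10 CPM. The camera adjusted p was 6.71e-24 for ribosomal proteins, 8.47e-07 for the proteasome, 0.000141 for heat shock and 3.72e-08 for oxidative phosphorylation, against 0.541 for each with an estimated correlation. Exact permutation of the scores gave adjusted p = 0.0282 for each, except 0.0391 for oxidative phosphorylation.

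These falls ran alongside a trend with the genomic span of genes. The median log2 fold change climbed from -0.31 in the decile of shortest genes to 0.38 in the decile of longest genes. The slope on log2 span of log2 CPM, centred for each gene on its mean over the 10 libraries, was higher by 0.102 in the ibudilast than in the untreated group (SD 0.0213 and 0.0343, n = 5 each; exact permutation p = 0.00794, the smallest the arrangements allow). Centring fixes where 0 lies, so only differences between libraries can be read from these slopes. Among the untreated libraries the slope rose with the replicate number, from -0.0885 in untreated 1 to -0.0016 in untreated 5. Ibudilast 1 followed at 0.0230. The ribosomal protein score likewise was 1.21 in untreated 1, 1.63 in untreated 2 and -0.13 in untreated 5. The homeostatic microglia score was 0.71 in untreated 1, 1.21 in untreated 2, 0.16 in untreated 5 and -0.037 in ibudilast 1. The slope and these scores thus also varied without treatment, and the cause of that was not tested. With the span trend removed, a fit added after seeing the data, the ribosomal protein median was -0.40 and that of the proteasome -0.19.

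**Figure D2:**
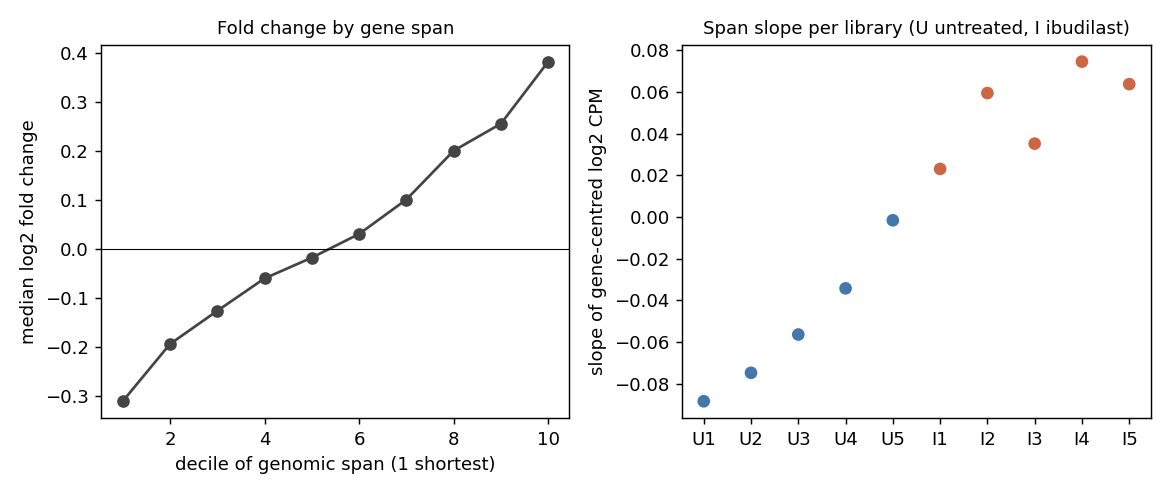
Left, median log2 fold change (ibudilast over untreated) in each decile of genes by genomic span, from -0.31 in the shortest to 0.38 in the longest. Right, slope on log2 span of log2 CPM, centred for each gene over the 10 libraries, in each untreated (U) and ibudilast (I) library, with a difference of 0.102 between the group means. The position of 0 follows from the centring.

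Most clock genes and some phosphodiesterase genes were higher. Of 15 circadian clock genes 11 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 0.58. The clock repressor gene Nr1d1 went from 109 ± 10.3 to 197 ± 34.5 CPM (SD, n = 5 each), and Arntl, which encodes the partner of CLOCK, from 24.2 ± 3.13 to 40.9 ± 7.81 CPM. With the hippocampal marker score as a covariate, where edgeR called 0 genes, the clock median was 0.39. Whether the groups were dissected at the same time of day was not among the labels used here. In the list of ibudilast targets and phosphodiesterases 7 of 21 rose and 1 fell, again 7 and 1 adjusted over the list alone. Pde4d, Pde4b and Pde4a, which encode enzymes that break down cAMP, rose by 1.63 ± 0.22, 1.07 ± 0.19 and 0.82 ± 0.15 on the log2 scale (SE), and Mif fell by 0.72 ± 0.15. Camera gave adjusted p = 0.000153 for the clock and 0.0388 for the targets, exact permutation of the scores 0.0282 for each, and the adjusted p was 0.541 for each with an estimated correlation. The targets had a median log2 fold change of 0.45. Their camera adjusted p was 0.0587 without untreated 4 (median 0.59), 0.0509 without ibudilast 1 (median 0.51), 0.221 with the span trend removed (median 0.33), and 0.289 and 0.075 with the neocortical and the hippocampal score as a covariate (medians 0.30 and 0.33).

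**Figure D3:**
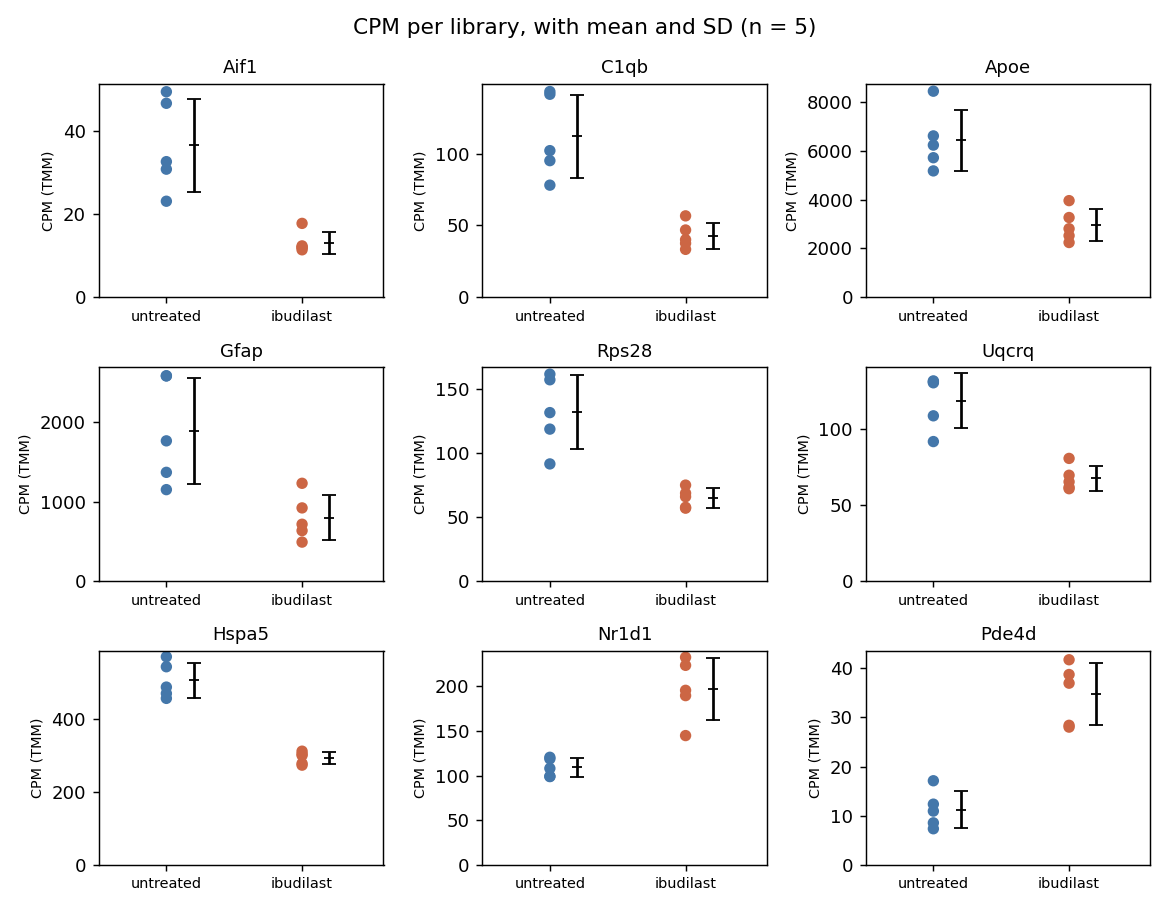
CPM of 9 genes in each of the 10 libraries, with the group mean and SD beside the points (n = 5 each) and every axis starting at 0. Aif1 averaged 36.4 and 13.1 CPM, Rps28 averaged 132 and 64.8 CPM, and Nr1d1 averaged 109 and 197 CPM in untreated and ibudilast libraries.

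Of 27 Alzheimer disease genes 9 rose and 5 fell (11 and 5 adjusted over the list alone). Bace1, which encodes the beta-secretase, went from 43.3 ± 12.8 to 92.2 ± 11.2 CPM (SD, n = 5 each), and the kinase gene Gsk3b from 25.3 ± 7.15 to 63.9 ± 15.3 CPM. Psenen, which encodes a small subunit of gamma-secretase, fell by 0.75 ± 0.13 on the log2 scale (SE). Rat App stood at 2602 ± 384 and 2905 ± 306 CPM (edgeR adjusted p = 0.364). Whether reads of the human transgene were counted as rat App is not given in the sources used here. The list did not pass camera (adjusted p = 0.266, or 0.541 with an estimated correlation) and passed the exact permutation of its score (adjusted p = 0.0391).

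Among glia, Aqp4, Gja1, Slc7a10 and Ntsr2 fell and the bicarbonate transporter gene Slc4a4 rose of 12 astrocyte markers, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.108). Without untreated 2, ibudilast 2, ibudilast 4 or ibudilast 5, Aqp4 did not pass either, and its log2 fold change was -0.54 with all libraries and -0.65 to -0.45 with 1 left out. In the reactive astrocyte list Gfap, C3 and Hspb1 fell of 12, with 2 lower adjusted over the list alone. C3 passed with 1 library left out only when that was untreated 5 or ibudilast 1, with log2 fold changes from -0.88 to -0.55 over the 10 such fits. The intermediate filament gene Gfap went from 1889 ± 670 to 798 ± 287 CPM (SD, n = 5 each). That list did not pass (camera adjusted p = 0.134), except without ibudilast 5 (0.0401). Of 14 oligodendrocyte precursor genes Neu4, Olig1, C1ql1 and Ptprz1 fell and Tnr rose, or 7 and 1 adjusted over the list alone, with a camera adjusted p = 0.113, an adjusted p = 0.541 with an estimated correlation, and an exact permutation adjusted p = 0.0282. Of 18 myelin genes 0 passed edgeR, and adjusted over the list alone again 0 (camera adjusted p = 0.377, or 0.046 without untreated 1).

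Endothelial and pericyte genes fell in 7 of 20 cases, or 8 with 1 higher adjusted over the list alone. Slco1c1, a thyroid hormone transporter gene, went from 109 ± 20.7 to 53.9 ± 3.54 CPM (SD, n = 5 each). The list had a camera adjusted p = 0.0374, an adjusted p = 0.604 with an estimated correlation, and an exact permutation adjusted p = 0.201. Camera did not pass without untreated 4 (0.0587), ibudilast 1 (0.112), ibudilast 2 (0.0513) or ibudilast 4 (0.136), and the median log2 fold change was -0.23 with all libraries and -0.33 to -0.15 with 1 left out.

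Some members of neuronal lists rose, as did 2337 of all 11682 tested genes, a share that the glutamatergic list did not reach. With the neocortical score as a covariate the medians of the presynaptic, glutamatergic and activity-regulated lists were -0.19, -0.30 and -0.30. Under that score camera called the activity-regulated list lower (adjusted p = 0.0111). Of 18 presynaptic vesicle genes 5 rose, among them Pclo, which encodes a scaffold of the active zone, from 199 ± 37.0 to 329 ± 49.6 CPM (SD, n = 5 each). The list missed the threshold (camera adjusted p = 0.0512) and passed without untreated 1 (0.046), untreated 3 (0.0248), untreated 5 (0.026), ibudilast 3 (0.00787) or ibudilast 5 (0.0493). Of 18 GABAergic interneuron genes Gad2, Slc32a1, Reln, Kcnip1 and Erbb4 rose (camera adjusted p = 0.182). The log2 fold change of Reln was 1.53, or 0.80 without ibudilast 3, and Reln did not pass without untreated 1, untreated 2, untreated 3 or untreated 4. Of 20 glutamatergic synapse genes Grin2a and Shank2 rose (camera adjusted p = 0.25, or 0.0257 without ibudilast 3). Adjusted over the list alone, the counts in these 3 lists were the same. Of 33 activity-regulated genes 7 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.459). Egr1, an early response gene, went from 54.7 ± 18.2 to 165 ± 89.6 CPM, whereas the neurotrophin gene Bdnf went from 63.6 ± 13.5 to 27.6 ± 12.8 CPM.

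Genes of other tissue stood out in single libraries. Meningeal fibroblast genes rose in 8 of 18 cases (10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.193), except without ibudilast 2 (0.0471) or ibudilast 4 (0.0308). The collagen gene Col1a2 stood at 185 CPM in ibudilast 3 and 223 CPM in ibudilast 5, against 4.52 to 12.2 CPM in the other libraries, and its log2 fold change was 3.79, or 3.06 without ibudilast 5. The choroid plexus transcript Ttr reached 2491 CPM in untreated 1, and the pituitary hormone gene Prl 48.1 CPM in ibudilast 1 and 16.7 CPM in ibudilast 3. Of 7 choroid plexus genes Slc13a4 rose and Calml4 fell, and the list did not pass (camera adjusted p = 0.631). Slc13a4 did not pass without untreated 2, untreated 3, untreated 4, untreated 5, ibudilast 3 or ibudilast 5, and its log2 fold change was 2.98 with all libraries and 2.39 to 3.54 with 1 left out. Of 6 ependymal cilia genes Tekt4 and Lrrc23 fell, with a camera adjusted p = 0.0543, an adjusted p = 0.541 with an estimated correlation, and an exact permutation adjusted p = 0.0391. Lrrc23 did not pass without untreated 1, untreated 2, untreated 4, ibudilast 2, ibudilast 4 or ibudilast 5, and its log2 fold change ran from -0.91 to -0.62 with 1 library left out. Camera passed for the ependymal list without untreated 2, untreated 3 or any 1 ibudilast library, with adjusted p from 0.0122 to 0.0426. Adjusted over the list alone, the counts of the choroid plexus and ependymal lists were the same.

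In 4 further lists genes moved without a call for the list. Of 13 neurogenesis genes 2 rose, among them Stmn1, and 1, Tubb2b, fell (camera adjusted p = 0.647), and of 29 autophagy and lysosome genes 3 rose and 8 fell (0.193). Of 20 glucocorticoid response genes 4 rose and 5 fell (0.691), and of 21 cholesterol synthesis genes 6 rose (0.25), with Stard4 rising by 1.40 ± 0.20 on the log2 scale (SE). Adjusted over the list alone, the counts in these lists were the same.

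**Figure D4:**
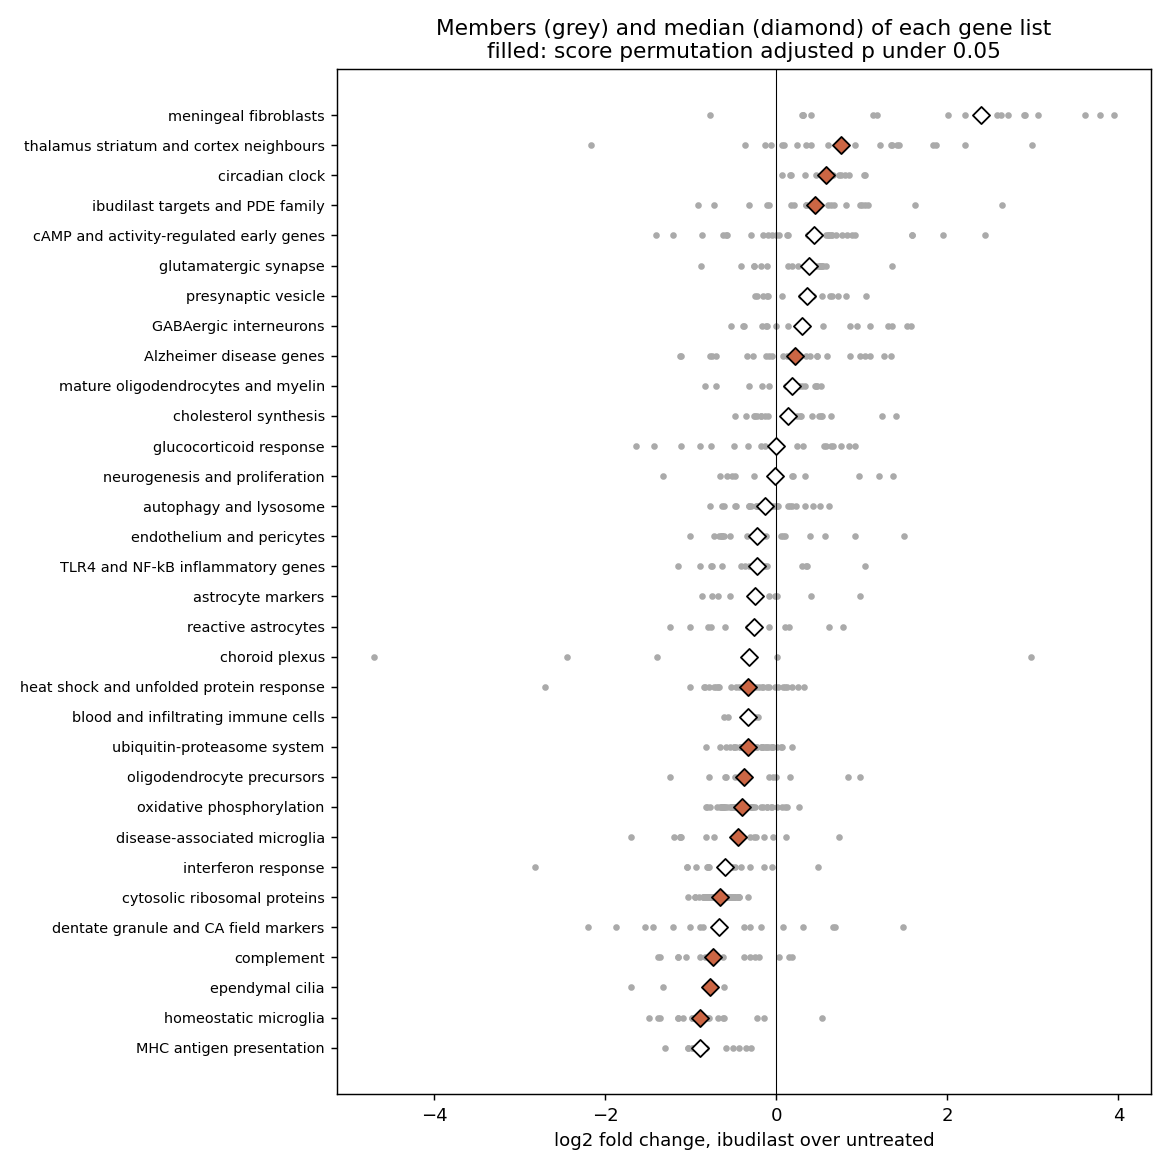
Log2 fold change (ibudilast over untreated) of each tested member (grey) and the median (diamond) of 32 gene lists, filled where the exact permutation of the list score had an adjusted p under 0.05. Ribosomal proteins have a median of -0.66 and clock genes of 0.58.

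In all, 13 of 32 lists passed camera with a preset correlation, 3 higher and 10 lower. Of 100 splits of the same libraries, 38 gave at least as many. With an estimated correlation 0 lists passed camera, with 2 at an unadjusted p under 0.05. The exact permutation of list scores passed for 13 lists, and fry for 15. The permutation compares the groups only, so with 4497 of 11682 genes changed a list can pass without differing from other genes.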

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

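Removal of the span trend, the hippocampal score as a covariate, the thinning, the test of tissue makeup on all changed genes and the weighing of a single library by the count of genes and by the list median were chosen after the data were seen, while the splits and the fits without each library were set before. For the list tests, a permutation p of the list score was required beside the camera call only after other splits of the libraries turned out to give many camera calls. Of 354 groups of 5 values examined, 22 had a sample far from the other 4, where chance gives about 1 in 20.

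In ibudilast 3, the score of cerebellar markers was 2.45, against at most -0.0283 in the other ibudilast libraries. Its heat shock list score was -0.927, and Car8 stood at 519 CPM and Reln at 650.2 CPM. Ibudilast 2 had 7.41% of its counts in ribosomal RNA, 10.3% in its 10 most abundant genes, and 6201 CPM of Mbp. Untreated 1 had a choroid plexus score of 1.58. Ibudilast 1 stood above the other ibudilast libraries at Aif1 (17.7 CPM), Amigo2 (11.6 CPM), Psmb10 (18.8 CPM) and Tubb2b (207.8 CPM), and below them at Sema3a (4.56 CPM) and Traf6 (5.08 CPM). Untreated 2 stood apart at Cacng5 (0.490 CPM), Fat2 (1.47 CPM) and Nr1d2 (97.3 CPM), untreated 3 at Ramp3 (1.504 CPM), untreated 4 at Lrrc10b (147 CPM) and Nr3c1 (88.3 CPM), and untreated 5 at Hspb1 (6.90 CPM) and Stat2 (52.4 CPM).

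Many genes changed, and a list of neighbouring-region markers was higher. Of 100 splits of the libraries only 1, the real one with 4497 genes, gave as many, and the highest other gave 492. Chance is argued against, though 100 splits cannot show a share below 1 in 100. Library depth is argued against, since thinning to the smallest total left 4388 genes, and so is a single library, since 3458 to 4751 genes changed without each library in turn. Different tissue makeup of the dissections may account for part of the pattern. The contrast of the neighbouring-region list with the dentate and CA list was higher in all 5 ibudilast libraries than in all 5 untreated ones (exact permutation p = 0.00794, the smallest the arrangements allow). That contrast largely restates the higher neighbouring-region list, so its p adds no separate evidence on the cause. An effect of ibudilast on the same genes stays open and untested, because makeup and treatment vary together here.

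Most genes in the ribosomal protein, respiratory and proteasome lists fell. A yield that follows gene span, as approximated here, is argued against as the whole cause for ribosomal proteins. Their median log2 fold change went from -0.66 to -0.40 with the trend removed (exact permutation p = 0.00794, the smallest the arrangements allow). A yield that depends on transcript length was not tested. The proteasome median went from -0.34 to -0.19 with the trend removed, and the list kept its calls (camera adjusted p = 0.0004, exact permutation p = 0.0159). For oxidative phosphorylation, where the median went from -0.40 to -0.28 and the permutation p to 0.0556, span and treatment cannot be told apart. Different tissue makeup of the dissections cannot be told apart from ibudilast either. With the neocortical score as a covariate the medians were -0.52 for ribosomal proteins, -0.44 for oxidative phosphorylation and -0.33 for the proteasome. Their camera adjusted p was 2.3e-13, 2.7e-08 and 3.0e-08. That score covers neocortical content only and also varies with treatment (-0.50 ± 0.13 in untreated and 0.50 ± 0.61 in ibudilast libraries, SD, n = 5 each). The ribosomal median was -0.63 with the hippocampal score as a covariate. The markers of that score were listed after their values were seen, so its difference between the groups is no evidence on makeup. As a mean z-score over the 10 libraries, it was 0.64 ± 0.25 in untreated and -0.64 ± 0.60 in ibudilast libraries (SD, n = 5 each) and so varies with treatment, and edgeR called 0 genes with it, with 1552 at an unadjusted p under 0.05, so a median kept under it, which had been set as evidence against makeup before that value was seen, excludes nothing.

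Most homeostatic microglia markers fell. A span trend, as approximated here, is argued against as the whole cause. With it removed the homeostatic list median was -0.69, from -0.89 before (exact permutation p = 0.00794). A single library is argued against too, with a camera adjusted p of at most 5.27e-05 and a median from -1.07 to -0.72 without each library in turn. Different tissue makeup of the dissections cannot be told apart from ibudilast, with a homeostatic median of -0.70 under the hippocampal covariate, for the reason given for ribosomal proteins. The disease-associated list did not pass under it (median -0.24, camera adjusted p = 0.115). Under the neocortical covariate the homeostatic median was not reduced (-0.98, camera adjusted p = 7.4e-06). The disease-associated list did not pass there (median -0.40, camera adjusted p = 0.16). The neocortical score covers neocortical content only and also varies with treatment, so other makeup stays open. The homeostatic score also varied among untreated libraries, from 1.21 in untreated 2 to 0.16 in untreated 5, and the cause was not tested. Fewer microglia, or fewer of these transcripts per cell, may follow from treatment or from the tissue sampled, and neither was tested.

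For the number of changed lists chance is not excluded, since 38 of 100 splits gave at least the 13 lists of the real grouping, and the highest other gave 20.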

How the results depend on the processing

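Settings with sets of libraries left out, covariates from markers, thinning, removal of ribosomal RNA and removal of the span trend were chosen after seeing the data. The count of 4497 changed genes stayed within 1.5 times under the alternatives set beforehand, from 3458 without untreated 1 to 5745 at an unadjusted p of 0.05, with DESeq2 at 4979 and limma-voom at 4384. Leaving out 1 library gave 3458 to 4751 genes, 1843 to 2573 higher and 1615 to 2284 lower. The share of higher genes was 52.0%, 60.1% with library size only and 45.2% with upper-quartile factors. With the neocortical score as a covariate 1740 genes were called (1199 higher, 541 lower). Of the 4497 main calls, 1234 kept their call and direction there. The hippocampal score as a covariate gave 0 calls (0 higher, 0 lower). Without ibudilast 3, ibudilast 5 and untreated 1, 1357 genes were lower and 21 lists changed. The cause was not tested. Camera called 13 lists, 11 to 16 with 1 library left out, and 0 with an estimated correlation. The permutation of list scores called 13 lists, and 0 to 12 with 1 library left out, with 0 without ibudilast 2 and 0 without ibudilast 3. It also called 0 without both ibudilast 3 and untreated 1, and 0 when ibudilast 5 was left out as well. In these last fits fewer arrangements raise the smallest possible p. Simulated 1.5-fold changes, at the depth, spread and group size of this comparison, were recovered in 18% of cases with 200 changed genes. Recovery depends on the share of changed genes, so 18% need not hold where 4497 were called.

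With the replicate number as a block, 3535 genes and 15 lists changed. Same-numbered libraries correlated between -0.127 and 0.0226 in their deviations and 0 libraries matched their own number best. Expression thus gave no sign that the numbers pair the animals, and no label says that they do. A pairing that leaves no trace in expression cannot be excluded this way. Of 135 named genes, 121 kept their call and direction without each library in turn, as did 22 of 32 lists in camera. With the neocortical score as a covariate 66 of the 135 named genes kept both, and with the hippocampal score 4 did. Both scores vary with treatment, so a call lost under them does not tell makeup from ibudilast.

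Directions turned as follows, with list medians given and the camera direction where it differs. The causes were not tested. With 1 library left out, the choroid plexus list ran from -1.24 to 0.42, turning without untreated 1 and, in camera, without ibudilast 4 (-0.65), and the glucocorticoid list from -0.19 to 0.17, with 0.12 and camera up without ibudilast 4. Without ibudilast 3 and untreated 1 the choroid plexus median was 0.17, and with ibudilast 5 also left out it was 0.17, with -0.049 for Tlr4 and -0.42 for meningeal fibroblasts. Removing the span trend gave -0.16 for App, 0.088 for the glutamatergic synapse list (camera down) and 0.049 for neurogenesis and proliferation. The neocortical covariate gave -0.040 for App, 0.0037 for Lrrc23, -0.30 for cAMP and activity-regulated early genes (camera adjusted p = 0.0111), -0.30 for the glutamatergic synapse, -0.19 for presynaptic vesicles, -0.28 for cholesterol synthesis and -0.33 for choroid plexus (camera up). The hippocampal covariate gave -0.66 for Car8, -1.03 for Fat2, 0.14 for Lrrc10b, and -0.067 for cAMP and activity-regulated early genes. It also gave -0.047 for dentate and CA markers, -0.037 for blood and immune cells and -0.12 for the glucocorticoid list, each with camera up. The neurogenesis and glucocorticoid medians also changed sign between scaling factors.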

Other observations

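All tests of gene families here were chosen after the values were seen, and 12 families were taken by symbol. The permutation of a family score does not compare the family with other genes, of which 4497 of 11682 changed. The direction of each family median was the same under TMM, RLE and upper-quartile factors and library size only. The families were not tested with a covariate from region markers. Different tissue makeup of the dissections thus cannot be told apart from ibudilast for them either. Of 72 genes for potassium channels and their partner proteins 40 rose and 3 fell, with a median log2 fold change of 0.78 (exact permutation of the family score, adjusted p = 0.0119; camera adjusted p = 3.82e-05, or adjusted p = 0.253 with an estimated correlation). Kcna2, which encodes a voltage-gated channel, stood at 4.86 to 8.83 CPM in untreated and 27.0 to 71.0 CPM in ibudilast libraries. Of 21 calcium channel genes 13 rose and 2 fell, and of 22 genes for kinesins, motors that carry cargo along microtubules, 9 rose and 1 fell (permutation adjusted p = 0.0119 for each, and adjusted p = 0.253 for each by camera with an estimated correlation). Among GABA-A receptor subunits 3 rose and 4 fell of 12, with Gabrb2 rising by 2.44 on the log2 scale and Gabra5 falling from 135.7 to 321.8 CPM in untreated to 35.5 to 148.7 CPM in ibudilast libraries, and the family did not pass (permutation adjusted p = 0.267).

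Both families of mitochondrial genes examined outside the respiratory chain had members on the lower side. Of 69 mitochondrial ribosomal protein genes 36 fell and none rose, with a median log2 fold change of -0.35, and of 19 mitochondrial import genes 12 fell and 1 rose (permutation adjusted p = 0.0119 for each, and adjusted p = 0.253 and 0.294 by camera with an estimated correlation). Zinc finger protein genes rose in 52 of 176 cases and fell in 5 (permutation adjusted p = 0.0119, and adjusted p = 0.294 with an estimated correlation). With the span trend removed, the camera adjusted p was 0.00141 for mitochondrial ribosomal proteins, 0.0391 for import, 0.000237 for potassium channels, 0.0495 for calcium channels and for kinesins, and 7.52e-06 for zinc finger proteins. Translation initiation factors (19 lower and 7 higher of 52) and lysine demethylases and methyltransferases (4 higher of 14) had permutation adjusted p = 0.0119, but adjusted p = 0.253 and 0.324 by camera with an estimated correlation and, for each, a camera adjusted p = 0.285 with the span trend removed. RNA polymerase subunits had 9 lower and 4 higher of 25 (permutation adjusted p = 0.0212, camera adjusted p = 0.0634, or 0.253 with an estimated correlation and 0.639 with the span trend removed), protocadherins 8 lower and 10 higher of 48 (0.589), and serotonin receptors 1 higher of 10 (0.77).

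Tyro3, a receptor tyrosine kinase gene, had the smallest p of all tested genes, with 148.7 ± 7.29 CPM in untreated and 396 ± 53.0 CPM in ibudilast libraries (SD, n = 5 each; edgeR adjusted p = 0.000226). It was picked after the values were seen.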
